A study of Pyrocoelia pectoralis with 6 samples.

How the data were processed

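RNA was measured in 6 libraries from male Pyrocoelia pectoralis, a firefly: 3 libraries of the luminous organ, which makes the light, and 3 of the non-luminous organ, a tissue that the labels do not describe further. Per the labels' protocols, total RNA was extracted with Trizol and libraries were made with a stranded mRNA kit. The labels do not say whether the 3 libraries of an organ came from separate animals or pools, so p-values measure the spread between these libraries, which may be partly technical.

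The values are FPKM, a read or fragment number scaled to gene length and library total, as deposited by the authors for 12533 genes and 6 libraries. No value column was left without a sample. Per the submitters' processing notes, Trimmomatic, HISAT2, HTSeq and R 3.2.0 were used, with no role given for each. The genome build, gene positions, the annotation, the strand setting of the counting and any filter are not given in the sources used here. Gene symbols, descriptions, Gene Ontology (GO) terms and KEGG pathways were taken from the same table, in which 9405 genes had a description and 8950 a symbol. Descriptions were assigned by similarity to proteins of other species, so many family members share 1 name. Genes are therefore given with their identifiers.

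Depth was read from the steps between low FPKM values, which are whole multiples of what 1 read is worth in a gene and a library. Of 11795 genes above 0 in at least 3 libraries, 99.87% gave whole reads within 0.05 of a whole number. The library totals behind the FPKM values came out between 18.04 and 20.42 M reads (M for mega), a ratio of 1.13 between the highest and the lowest. On 3000 simulated genes the procedure returned the reads exactly up to a common factor per gene, wherever it found a step. Setting that factor from whole gene lengths was not part of this check. Floors and read numbers cover counting error only. A gene with no read in an organ was set against a floor of 3 reads over the 3 libraries of that organ.

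Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1. Genes with a mean of at least 1 FPKM over the 6 libraries were kept, which left 9863 genes. The luminous organ was compared with the non-luminous organ by a linear model without a block (lmFit, eBayes with an intensity trend, two-sided). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are luminous minus non-luminous on the log2(FPKM + 1) scale, which understates the change of low genes. In simulated data, 200 of 9847 genes were changed, 100 of them 2-fold and 100 of them 4-fold. Noise came from each gene's spread in these libraries, capped, with counting noise added again. Of the changed genes, 38% of those changed 2-fold and 81% of those changed 4-fold were called, and 5 of 124 calls were unchanged genes. Far fewer genes were changed than were called in the real data, which makes the adjustment of p stricter. These percentages therefore do not carry over to the real comparison. With no change simulated, 0 genes and 0 lists were called. Each gene's noise was simulated independently of the other genes. The 0 lists therefore do not show how the list test behaves where members vary together.

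Gene lists were 36 sets defined by words in gene names or descriptions, 27 for pathways and 9 for tissues that a dissected organ could hold. Each list with at least 5 tested members (35 lists) was tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Matching by words takes in some members that do not belong, which are named where they matter. GO terms and KEGG pathways with 10 to 500 tested genes were tested by one-sided Fisher's exact tests for genes higher and for genes lower, against the tested genes that carried any term (8020 genes for GO, 3320 for KEGG), with Benjamini-Hochberg adjustment over 3746 tests. Genes are not independent, so these tests describe the gene sets and do not add samples.

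Named genes followed a rule. It took the 12 largest differences in each direction among called genes with non-overlapping groups and an informative name, the 5 most abundant genes of each organ, and up to 2 called members per list and direction. It also took the 5 most abundant called members of the luciferase list, up to 6 called homeobox genes and up to 4 called genes of nitric oxide, octopamine and cyclic GMP signalling. The text uses a subset, and genes chosen after their values were seen are said to be so. The design, the gene lists, the rule and the alternatives, other than those said to be added, were fixed before the data were examined. Alternatives were other pseudocounts, other filters on low values, median-of-ratios rescaling, quantile normalization, no trend, the replicate number as a block and each library left out in turn. A voom fit on the recovered reads, the alternatives for the annotation terms, the count of called list members under rescaling and with each library left out, and the luciferase list counted in its 2 kinds of enzyme were added after seeing the data. Replicates of 1 organ were checked for being the same library. Over genes with at least 20 reads, chi-square per gene was 33.1 to 98.4 for the 6 pairs, far above sampling noise, and each library was counted once. The R package data.table (version 1.17.8) was also used.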

Results

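Messenger RNA of the luminous organ and of the non-luminous organ of male Pyrocoelia pectoralis was compared in 3 libraries per organ. The labels state no question beyond sequencing the transcriptome. Library totals were 20.04, 20.42 and 18.95 M reads for luminous replicates 1, 2 and 3, and 18.86, 18.37 and 18.04 M reads for the non-luminous replicates. The libraries separated first by organ. Principal component 1 held 69.7% of the variance and parted the organs. Component 2 held 15.7% and set luminous replicate 1 apart from luminous replicates 2 and 3. Across genes, which are not independent replicates, Pearson's r of log2 values was 0.979 to 0.981 within the non-luminous organ, 0.948 to 0.974 within the luminous organ and 0.863 to 0.924 between organs.

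**Figure D1:**
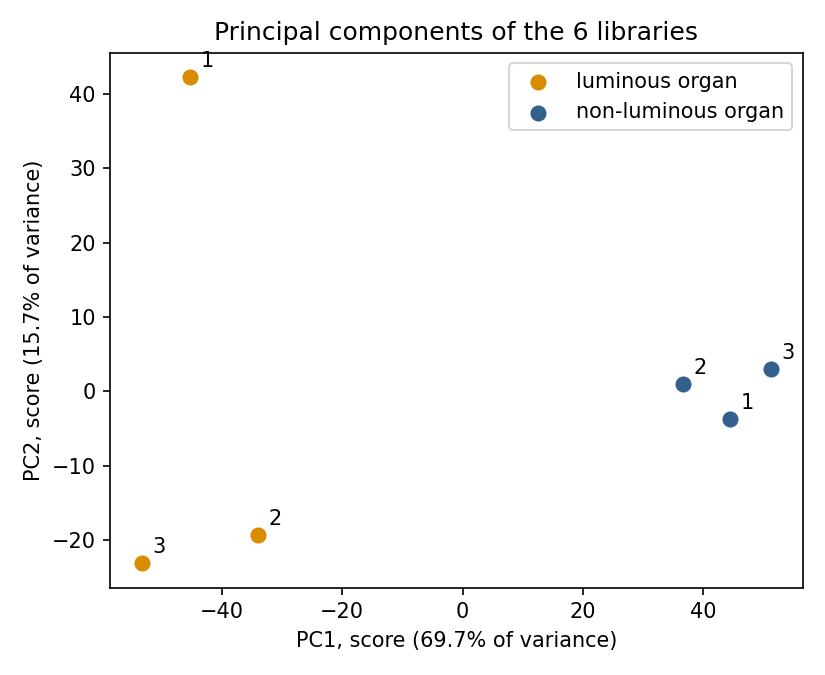
Scores of the 6 libraries on principal components 1 (x axis) and 2 (y axis) of centred log2(FPKM + 1), with points coloured by organ and numbered by replicate. The organs part on component 1 (69.7% of variance), and luminous replicate 1 lies apart on component 2 (15.7%).

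A gene described as a luciferase, the enzyme that oxidises luciferin to give light, marked the luminous libraries. The description rests on similarity and is shared by other genes, and whether this gene makes the light was not tested. The gene RI129_003463, described as luciferin 4-monooxygenase, stood at 399 ± 122 FPKM in the luminous organ and 0.474 ± 0.139 FPKM in the non-luminous organ (SD, n = 3), an 842-fold ratio of means. Its log2 difference was 8.05 (SE 0.223, limma adjusted p = 4.02e-06), and it was read 39244 times in the 3 luminous libraries against 43 times in the others. It ranked 268 among all genes of the luminous organ by mean FPKM. The gene hsdl2 (RI129_001276), described as hydroxysteroid dehydrogenase-like protein 2, stood at 220 ± 112 FPKM with no read in any non-luminous library, and was at least 5070-fold higher than the floor of 3 reads over the organ (limma adjusted p = 5.61e-05). A serine hydrolase-like gene, serhl (RI129_008074), was higher by 5.80 on the log2 scale, and the fatty acid-binding protein gene RI129_001902 by 5.51, a call that was lost in a voom fit on recovered reads chosen after seeing the data (adjusted p = 0.0949, with 5e-04 to 0.0949 over all alternatives).

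PAPSS2 (RI129_010993), which makes the sulfate donor PAPS, rose from 1.84 ± 0.349 to 95.3 ± 60.7 FPKM (SD, n = 3; log2 difference 4.85). A luciferin sulfotransferase gene, LST (RI129_005665), an enzyme family that uses PAPS to form sulfoluciferin, rose from 3.14 ± 1.12 to 55.7 ± 21.4 FPKM (log2 difference 3.73). The trehalose transporter gene Tret1 (RI129_009288) was higher by 4.70, the cytochrome P450 gene Cyp4g15 (RI129_007518) by 5.20 and the fatty acyl-CoA reductase gene CG5065 (RI129_012914) by 3.39. The receptor kinase gene Cad96Ca (RI129_001390) rose from 10.2 ± 1.32 to 152 ± 85.1 FPKM, and the aminoacylase gene ACY1 (RI129_001233) was higher by 3.17. Each of these was called by limma, with adjusted p between 6.37e-05 and 0.00234, and under all alternatives run.

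On the log2(FPKM + 1) scale, genes lower in the luminous organ had larger differences still. That order depended on the setting: over the alternatives hsdl2 reached 13.18, and the gene RI129_004336 no further than -12.49. The unnamed gene RI129_004336 was among the 5 most abundant of the non-luminous organ, at 14470 ± 4800 FPKM, and stood at 2.49 ± 0.989 FPKM in the luminous organ (SD, n = 3; log2 difference -11.99, SE 0.298). Digestive enzyme genes followed: chymotrypsin BI (RI129_002540) fell from 3467 ± 757 to 0.778 ± 0.740 FPKM, and the zinc carboxypeptidase gene AGAP009593 (RI129_011196) from 735 ± 489 to 1.11 ± 0.169 FPKM. Obp69a (RI129_011032), described as an odorant-binding protein, fell from 180 ± 109 to 0.0402 ± 0.0696 FPKM, and the trypsin gene deltaTry (RI129_013174) from 122 ± 54.9 to 0.0216 ± 0.0374 FPKM. The glutathione S-transferase gene GstD1 (RI129_006451) had no read in any luminous library and was at least 817-fold lower than its 63.1 ± 40.3 FPKM in the non-luminous organ. A juvenile hormone esterase gene, Tcjhe (RI129_009409), differed by -6.67 and stood at 6.12 FPKM in luminous replicate 1 against 0.787 and 0.660 FPKM in luminous replicates 2 and 3. The purine nucleoside phosphorylase gene pnp (RI129_008697) fell by 5.92 on the log2 scale.

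**Figure D2:**
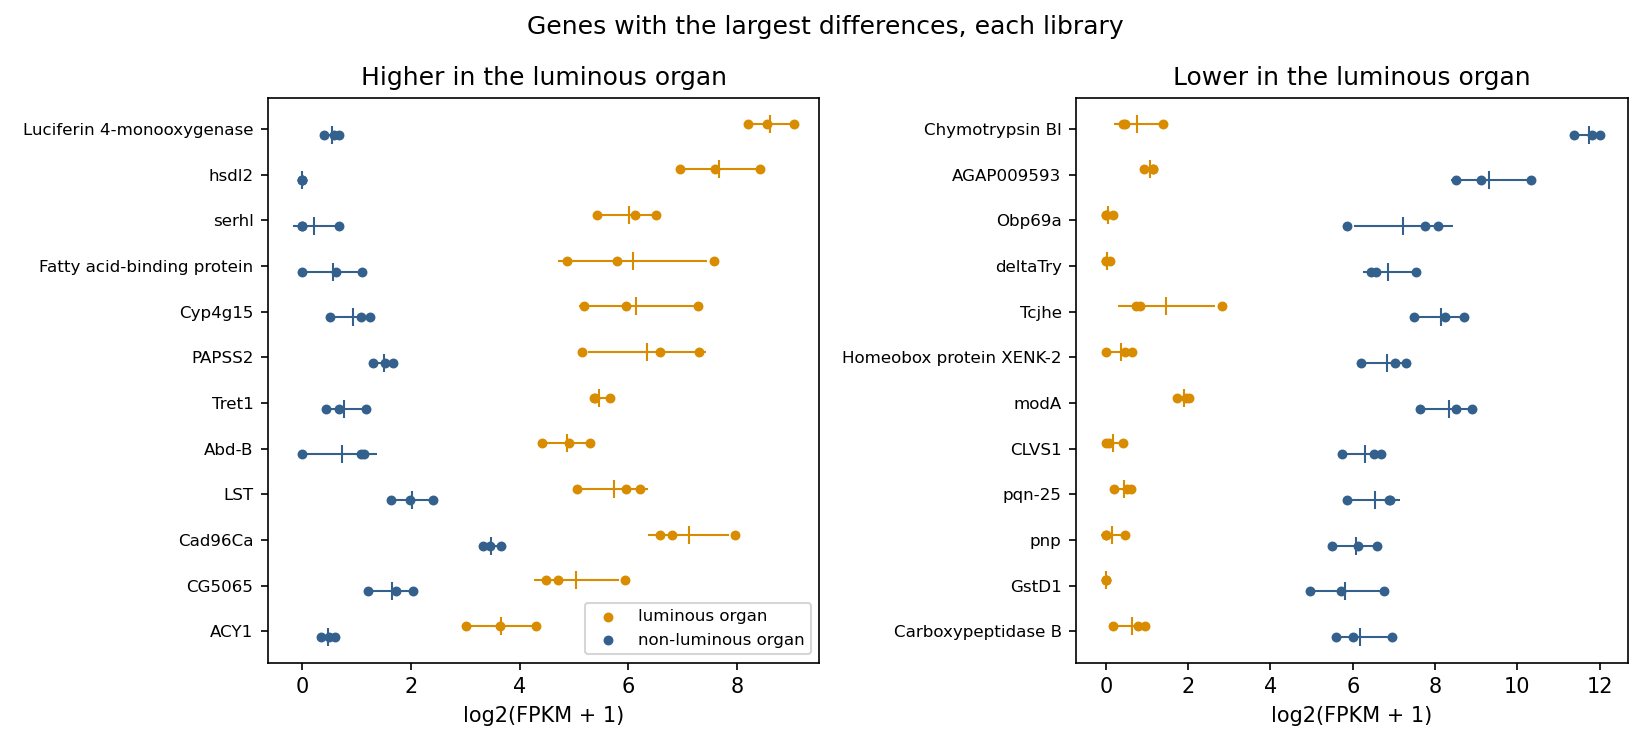
Expression as log2(FPKM + 1) (x axis) of the 12 genes with an informative name and the largest positive (left) and of the 12 with the largest negative (right) differences; points are libraries, ticks are means of 3 and bars are SD. By the rule, only called genes whose luminous and non-luminous libraries do not overlap could be chosen.

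In all, limma called 2626 of 9863 genes, 950 higher and 1676 lower in the luminous organ, and 1382 of them differed at least 2-fold (367 higher, 1015 lower). The groups did not overlap for 46.1% of tested genes, where chance gives 10%. The split between directions depended on scaling: 36.2% of calls were higher as deposited, 46.2% after median-of-ratios rescaling and 53.8% after quantile normalization, which moved the median difference of all genes from -0.095 to -0.004 and 0.074. The count also moved with 1 library left out. It was 1606 without luminous replicate 3, 1532, 1577 and 1119 without non-luminous replicates 1, 2 and 3, and 2648 and 2618 without luminous replicates 1 and 2. Here and below, a fit with 1 library fewer has less power. A call lost in it therefore need not mean that the call rests on that library. For differences of at least 2-fold it was 809 without non-luminous replicate 3 and 863 with a pseudocount of 5.

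More genes of the luciferase and luciferin enzyme list were lower than higher. Of 39 tested members, 3 were higher, 23 lower and 13 not called (5 higher and 26 lower adjusted over the list alone), with a median log2 difference of -1.11. The list joins unrelated enzymes, counted apart after the values were seen. Of 21 genes described as luciferin 4-monooxygenase, 2 were higher and 12 lower, and of 18 luciferin sulfotransferases, 1 was higher and 11 lower. The sulfotransferase genes LST RI129_003358 and LST RI129_009180 differed by -3.15 and -3.13, and the luciferase-like gene RI129_011076 fell from 43.2 ± 16.6 to 6.095 ± 1.498 FPKM (SD, n = 3). The most abundant member, RI129_011075, chosen after its values were seen, was high in both organs, at 502 ± 135 and 333 ± 23.2 FPKM, and did not pass (limma adjusted p = 0.0623, with 0.0362 without luminous replicate 1, 0.0403 after quantile normalization and 0.0362 to 0.186 over all alternatives). Luciferase-like proteins include fatty acyl-CoA synthetases, and several of these genes have neighbouring identifiers and 1 shared name, so how reads were divided between similar copies is not known. Camera adjusted p for the list was 0.00492, and adjusted p was 0.444 with an estimated correlation and 0.14 with a minimum of 5 FPKM (0.00102 to 0.14 over the other alternatives). With a minimum of 5 FPKM, only 12 sulfotransferases and 13 other members were tested, and 16 members were called. With all 39 tested, the count of called members was 16 without luminous replicate 3 and 16, 15 and 11 without non-luminous replicates 1, 2 and 3. Of the monooxygenase genes, 5, 6, 6 and 4 were lower without these libraries in turn, and of the sulfotransferases 9, 8, 7 and 5. After quantile normalization 15 of the 39 were lower and 5 higher. The median log2 difference of the list was then -0.724. It was -0.551 with a pseudocount of 5, -0.733 with no filter on low values and -1.157 with a pseudocount of 0.1.

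**Figure D3:**
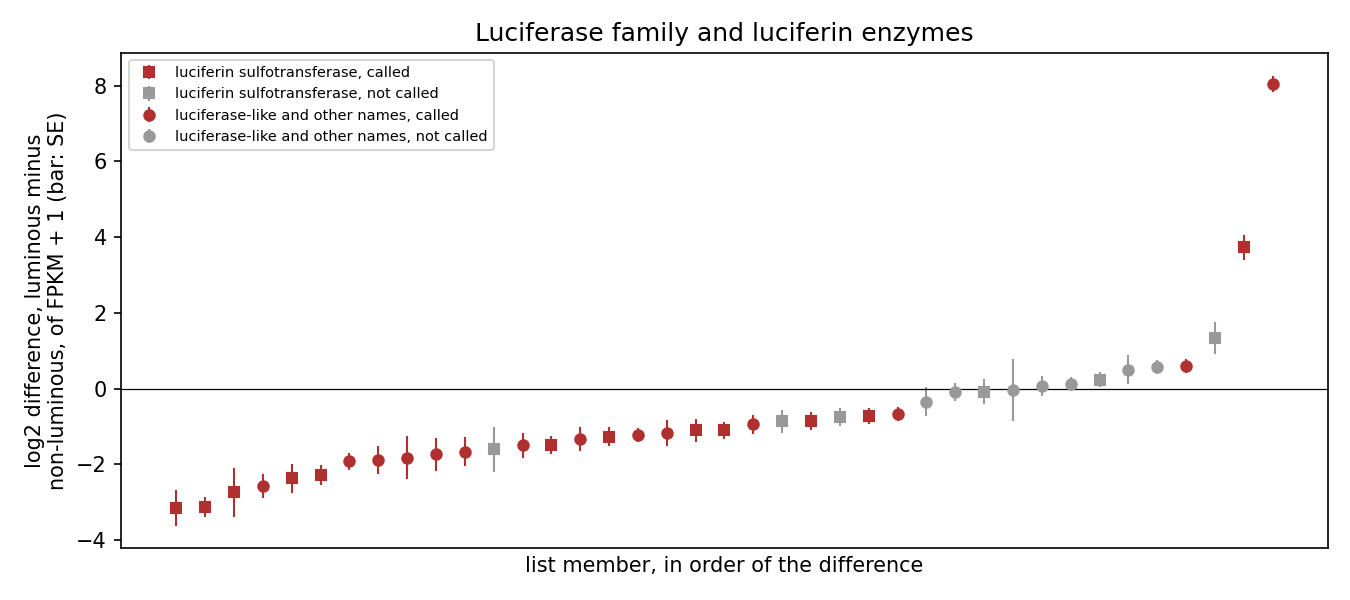
Log2 difference of FPKM + 1, luminous minus non-luminous (y axis, bars SE), of the 39 tested members of the luciferase and luciferin enzyme list in order of the difference (x axis); squares are luciferin sulfotransferases and red marks called members. Of these, 3 lie above 0 and 23 below.

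The homeobox gene Abd-B was among the largest differences. Hox genes set segment identity along the body, and Abd-B (RI129_000704) marks its most posterior segments. The labels give no body position for the non-luminous organ. For the Hox genes, body position therefore cannot be told apart from being luminous. Abd-B rose from 0.775 ± 0.672 to 29.3 ± 9.15 FPKM (SD, n = 3; log2 difference 4.14, SE 0.367) and was called under all alternatives run. The gene RI129_007335, described as homeobox protein XENK-2, fell from 119 ± 42.5 to 0.306 ± 0.278 FPKM. The homeobox genes cad (RI129_007050, 2.07) and otp (RI129_003717, 2.31) were higher. The call of cad was lost without luminous replicate 3 (limma adjusted p = 0.0755, range 0.0136 to 0.0755), and that of otp without non-luminous replicate 3 (adjusted p = 0.0501, range 0.0139 to 0.0501). Chosen after their values were seen, ABD-A differed by 1.46 and Ubx, Antp and Scr by -0.76, -0.69 and -0.85, with limma adjusted p of 0.0363, 0.0358, 0.0467 and 0.0421. These 4 calls were weak, and each was lost without non-luminous replicate 3. That of ABD-A was also lost without luminous replicates 2 and 3, that of Ubx without luminous replicate 3 and non-luminous replicates 1 and 2, that of Antp without any other library but luminous replicate 3, and that of Scr without any other library. Over all alternatives adjusted p ranged from 0.0208 to 0.0896, 0.0265 to 0.12, 0.0427 to 0.155 and 0.0274 to 0.125.

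Of 45 tested homeobox genes, 9 were higher, 6 lower and 30 not called (9 and 7 adjusted over the list alone). Camera adjusted p was 0.0454, and adjusted p was 0.438 with an estimated correlation and 0.0256 to 0.282 over the other alternatives. Without luminous replicates 2 and 3 in turn, 7 and 4 homeobox genes were higher and 4 and 3 lower. Without non-luminous replicates 1, 2 and 3 in turn, 6, 6 and 3 were higher and 2, 2 and 1 lower, and median-of-ratios rescaling and quantile normalization gave 10 and 16 higher and 2 and 2 lower.

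Many muscle genes and some genes of mitochondrial oxidative phosphorylation were higher. Of 27 muscle genes, 15 were higher and 1 lower (17 and 1 adjusted over the list alone). Tropomyosin (RI129_001915) rose from 1198 ± 192 to 3131 ± 289 FPKM (SD, n = 3; log2 difference 1.39), and Zasp52 (RI129_005438), a protein of the sarcomere's Z disc, rose by 1.38 on that scale. The gene TNT (RI129_000397), for troponin T, chosen after its values were seen, rose from 1476 ± 164 to 3381 ± 480 FPKM. The lower member, Dr, is a homeobox gene caught by its name. Of 56 genes of mitochondrial oxidative phosphorylation, 19 were higher and 0 lower (20 and 0 adjusted over the list alone, and 37 not called), among them SdhB (RI129_006380, 0.65) and SdhD (RI129_003422, 0.68), subunits of succinate dehydrogenase. Camera adjusted p was 1.16e-08 for muscle and 4.96e-09 for oxidative phosphorylation, and adjusted p was 0.438 and 0.197 with an estimated correlation. Between 11 and 14 muscle genes were higher with 1 library left out. For oxidative phosphorylation, 8 genes were higher without luminous replicate 3, and 11, 8 and 6 without non-luminous replicates 1, 2 and 3.

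Digestive, detoxifying and purine genes were lower as groups. Here, and for the single digestive genes above, the tissue held by each sample cannot be told apart from expression within cells. The design confounds both with the organ, and the labels do not describe the non-luminous organ. Of 91 midgut digestion genes, 47 were lower and 6 higher (51 and 8 adjusted over the list alone). Of 155 cytochrome P450 genes, 79 were lower and 8 higher (85 and 10), including spo (RI129_013246), of ecdysone synthesis, at 33.15 ± 10.97 against 0.409 ± 0.441 FPKM (SD, n = 3) and CYP6J1 (RI129_007663), with a log2 difference of -4.13. Of 94 glutathione S-transferase and UDP-glycosyltransferase genes, 50 were lower and 5 higher (53 and 7). Of 22 purine and urate genes, 15 were lower and 1 higher (15 and 1), among them XDH (RI129_006018), xanthine dehydrogenase, which makes urate and fell from 19.6 ± 7.95 to 0.902 ± 0.765 FPKM. Of 56 genes of ecdysone and juvenile hormone, 26 were lower and 4 higher (27 and 4). Camera adjusted p was 3.21e-06, 4.62e-07, 9.56e-06, 0.000106 and 0.00126 in that order, and adjusted p was 0.351, 0.542, 0.438, 0.438 and 0.438 with an estimated correlation. Without luminous replicate 3, and without non-luminous replicates 1, 2 and 3, the cytochrome P450 genes lower were 43, 43, 40 and 35 and those of ecdysone and juvenile hormone 17, 19, 15 and 13. Without the same libraries in turn, cytochrome P450 genes higher were 4, 4, 5 and 3, transferase genes higher 3, 2, 1 and 1, hormone genes higher 2, 3, 3 and 2 and purine and urate genes higher 0 each. Cytochrome P450 genes higher were 14 without luminous replicate 1 and 13 after quantile normalization, which gave 10 transferase genes higher. Without non-luminous replicate 3, 31 midgut genes and 33 transferase genes were lower, and purine and urate genes lower stayed between 12 and 15 with any library left out.

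Lipid and cuticle genes went both ways. Of 53 genes of fatty acid synthesis, elongation and reduction, 17 were higher and 11 lower (22 and 13 adjusted over the list alone). The desaturase gene RI129_001631 was higher by 2.39, while the fatty acid synthase gene Fasn RI129_001907 differed by -2.74. Of 37 cuticle genes, 8 were higher and 4 lower (9 and 4): SgAbd-1 (RI129_005049), an endocuticle protein gene, rose from 45.04 ± 12.06 to 382 ± 111 FPKM (SD, n = 3), and the chitin synthase gene chs-2 (RI129_006630) fell from 13.8 ± 5.32 to 0.115 ± 0.0410 FPKM. Of 17 genes named for the clock or opsins, 5 were higher and 0 lower (6 and 0), of which 4 were daywake genes and the other was Clk (RI129_008982), chosen after its values were seen. Its limma adjusted p was 0.0416, and the call was lost without luminous replicates 1 and 3 and without each non-luminous replicate in turn (range over all alternatives 0.0183 to 0.14). The gene dyw RI129_008645 stood at 497 ± 90.9 against 214 ± 28.3 FPKM. Camera adjusted p was 0.00576, 0.00576 and 0.00107, and adjusted p was 0.58, 0.46 and 0.438 with an estimated correlation. Without luminous replicate 3 and non-luminous replicates 1, 2 and 3, genes higher numbered 7, 7, 10 and 5 for fatty acid synthesis (7, 7, 6 and 7 lower), 5, 5, 4 and 3 for cuticle (5, 4, 4 and 5 lower), and 2, 1, 3 and 1 for the clock. Without luminous replicate 1 they were 21, 12 and 8, and the cuticle list was not called with a minimum of 5 FPKM (camera adjusted p = 0.134) or by fry (adjusted p = 0.154), with a lowest adjusted p of 0.000563 over the alternatives. After quantile normalization 15 cuticle genes were higher and 4 lower.

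Ribosomal, proteasome and V-ATPase genes had small median differences of 0.27, 0.14 and 0.30, with few single calls: 4 of 62, 1 of 34 and 3 of 17 higher, and 1 V-ATPase gene lower (0, 1 and 3 higher adjusted over the list alone). Camera adjusted p was 2.61e-07, 0.000764 and 0.0283, and adjusted p was 0.659, 0.692 and 0.692 with an estimated correlation. After quantile normalization the ribosomal and V-ATPase lists were not called (adjusted p = 0.136 and 0.142). Without luminous replicate 1 the proteasome and V-ATPase lists were not called (0.0519 and 0.649), nor was V-ATPase without non-luminous replicate 1 (0.0635). Over the other alternatives the lowest adjusted p were 3.43e-09, 5.24e-06 and 0.0022. Single calls moved too: ribosomal genes higher were 2 and 10 without luminous replicates 1 and 2, and 0, 0, 0 and 1 without luminous replicate 3 and non-luminous replicates 1, 2 and 3. Medians also moved. Without luminous replicate 1 those of proteasome and V-ATPase were 0.061 and 0.004, and the ribosomal median after quantile normalization was 0.134. Without luminous replicate 2 the ribosomal, proteasome and V-ATPase medians were 0.339, 0.246 and 0.446.

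Camera called 15 of 35 lists in all, 9 higher and 6 lower, but 0 with an estimated correlation, where 2 had an unadjusted p under 0.05. Fry, which does not compare a list with other genes, called 14, of which 3 were higher and 11 lower. It called 9 of camera's 15 and not the homeobox, fatty acid synthesis, ribosomal, proteasome, V-ATPase and cuticle lists (adjusted p = 0.112, 0.154, 0.166, 0.275, 0.42 and 0.154). Camera's preset also called up to 16 lists in other splits of the same 6 libraries, each of which set 2 libraries of an organ and 1 of the other against the rest and so kept part of the organ difference.

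**Figure D4:**
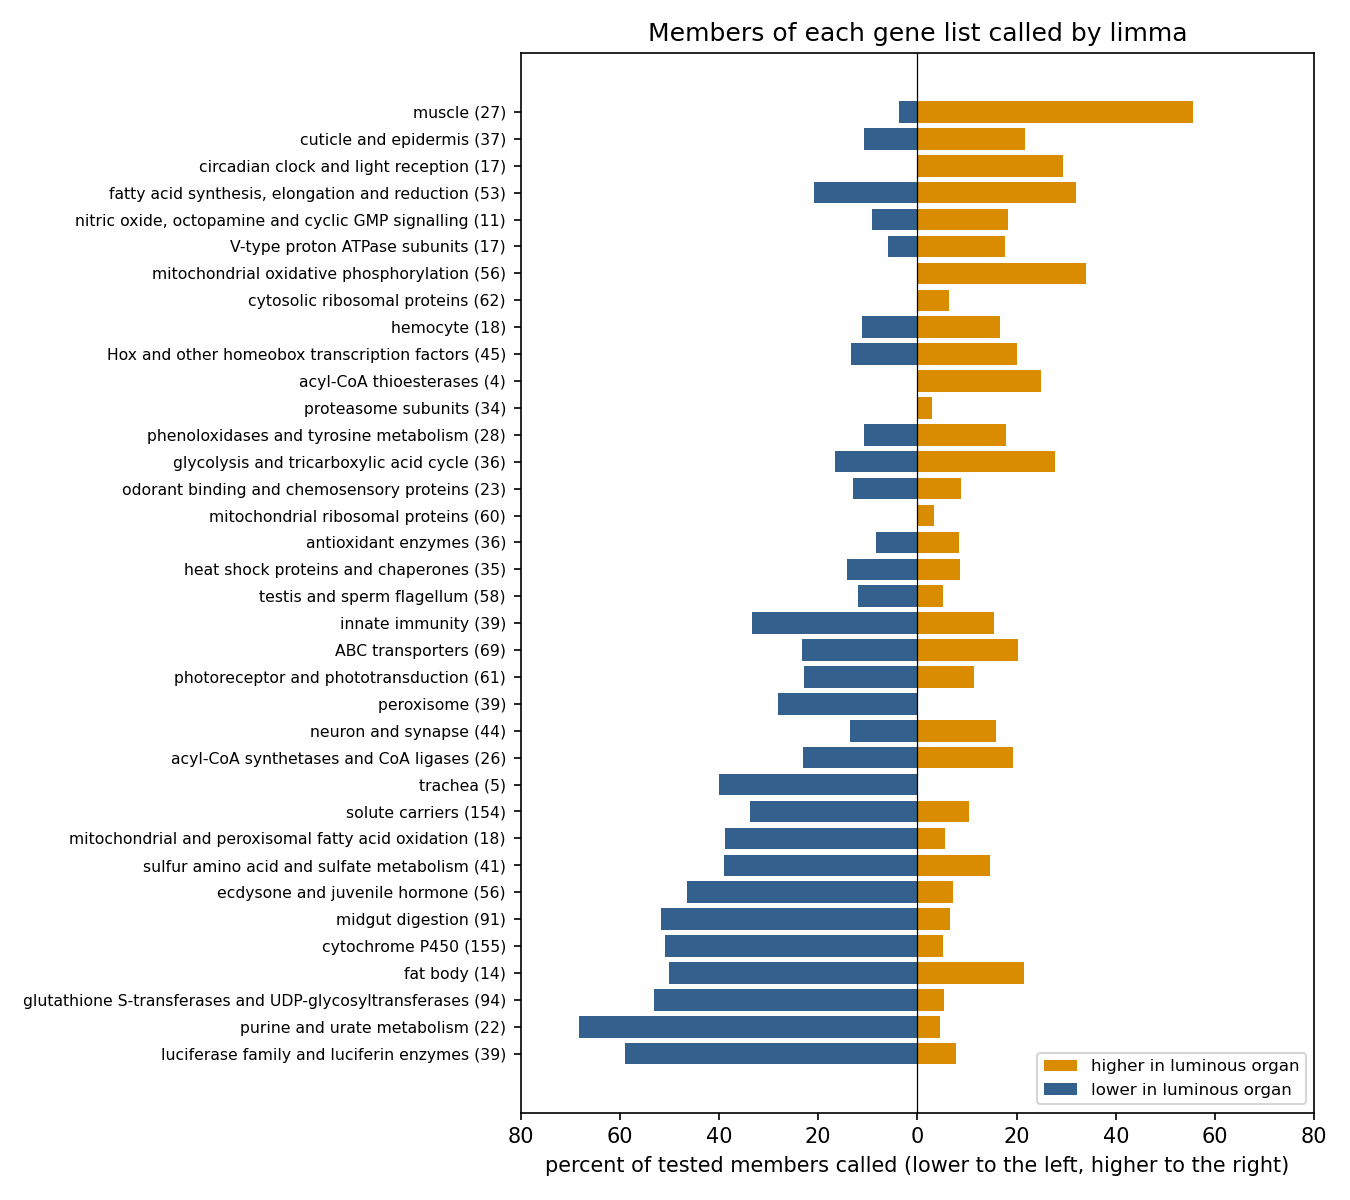
Percent of tested members called by limma (x axis; lower to the left in blue, higher to the right in orange) for each of 36 lists, ordered by median log2 difference, with tested members in brackets. For the luciferase and luciferin enzyme, midgut digestion and cytochrome P450 lists more members lie to the left, and for muscle and oxidative phosphorylation more lie to the right, as also after median-of-ratios rescaling and quantile normalization.

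The deposited annotation gave 31 terms for genes higher and 83 for genes lower. Among genes higher, cardiac muscle contraction held 14 called genes where 2.9 were expected (Fisher's exact test, adjusted p = 5.15e-05), oxidative phosphorylation 20 for 6.5 (adjusted p = 0.000535) and fatty acid elongase activity 6 for 1.1 (adjusted p = 0.0158). Terms can share genes, and the overlap of cardiac muscle contraction with oxidative phosphorylation was not counted. Among genes lower, heme binding held 95 for 34.3 (adjusted p = 3.22e-20), peroxisome 54 for 22 (adjusted p = 9.65e-09) and bioluminescence 12 for 3.6 (adjusted p = 0.00341). The bioluminescence term had 21 tested genes, 12 of them lower, the same numbers as the luciferin 4-monooxygenase genes counted above. It may hold the same similarity-named genes and is not separate support. Trehalose transport held 25 for 11.9 among genes lower (adjusted p = 0.00757), the opposite direction to Tret1 RI129_009288. The total of 114 terms was 61 with a minimum of 5 FPKM, and 52 and 60 without non-luminous replicates 2 and 3. The 31 terms for genes higher were 18 with that minimum, 18 without luminous replicate 3 and 12 and 6 without non-luminous replicates 2 and 3, and the 83 for genes lower were 43, 58, 40 and 54.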

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

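The voom fit on recovered reads, all alternatives applied to the annotation terms, and the list members counted under alternatives, other than the whole luciferase list, were chosen after seeing the data; the others were planned. The planned quasi-likelihood count test was not run because the values are FPKM. Of the called genes, 2335 of 2626 were called in the same direction after median-of-ratios rescaling, 2207 after quantile normalization, and 2433 in the voom fit, which called 2582 genes; none was called in the opposite direction under any alternative. With 1 library left out, counts were 1119 to 2648 for called genes, 809 to 1549 for genes at least 2-fold different, 11 to 26 for luciferase list members and 52 to 122 for terms. A pseudocount of 5 gave 863 genes at least 2-fold different. A minimum of 5 FPKM gave 16 luciferase list members and 61 terms, with fewer genes tested. Camera with an estimated correlation gave 0 lists. The cause was not tested for the other changes. Abundant genes that were not called changed sign: RI129_011505 to -0.04 without luminous replicate 3 and -0.047 without non-luminous replicate 1 (up to 0.089 with 1 library left out), and Tctp to -0.05 without non-luminous replicate 1 (up to 0.17). Of 145 named genes that were called, 88 were called under every alternative run. Equal replicate numbers showed no sign of pairing: deviations from the organ means correlated at -0.111, -0.009 and -0.166 across genes. Luminous replicate 3 with non-luminous replicate 1 gave 0.207. With 3 libraries per organ, these values cannot tell whether equal numbers shared animals or handling. With the replicate number as a block, 1996 genes (668 higher, 1328 lower), 1274 genes at least 2-fold different, 15 lists, 19 luciferase list members and 108 terms were called. At these depths of 18.04 to 20.42 M reads, genes near 1 FPKM rest on few reads.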

Other observations

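The tests of patterns and of other splits, and the genes named with the patterns, were chosen after the results were seen. The counts of list members in the main fit were planned, and those under alternatives were added after seeing the data. Of 41 genes of sulfur metabolism, 6 were higher and 16 lower (8 and 19 adjusted over the list alone), where 18 genes are luciferin sulfotransferases that are also luciferase list members. Of 154 solute carriers, 16 were higher and 52 lower (22 and 60), of 69 ABC transporters 14 and 16 (17 and 17), of 39 innate immunity genes 6 and 13 (8 and 16), and of 36 glycolysis and citric acid cycle genes 10 and 6 (11 and 7). Peroxisome genes had 0 of 39 higher and 11 lower (0 and 13), and fatty acid oxidation 1 of 18 higher and 7 lower (1 and 8). Acyl-CoA synthetases had 5 of 26 higher and 6 lower (7 and 7), antioxidant enzymes 3 of 36 and 3 (3 and 2), chaperones 3 of 35 and 5 (3 and 5), and mitochondrial ribosomal proteins 2 of 60 and 0 (0 and 0). Phenoloxidase and tyrosine genes had 5 of 28 higher and 3 lower (6 and 3), and 11 and 0 without luminous replicate 1, where camera adjusted p was 0.000206 against 0.119 with it. Signalling by nitric oxide, octopamine and cyclic GMP had 2 of 11 higher and 1 lower (2 and 1), where Octbeta2R (0.70) was lost with any 1 library left out (adjusted p 0.052 to 0.126) and Pde9 differed by -1.58.

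Of the tissue lists, fat body had 3 of 14 genes higher and 7 lower (4 and 8 adjusted over the list alone), neuron 7 of 44 and 6 (7 and 11), and photoreceptor 7 of 61 and 14 (8 and 15). Testis had 3 of 58 higher and 7 lower (1 and 1), hemocyte 3 of 18 and 2 (3 and 2) and trachea 0 of 5 and 2 (0 and 2). Of pathway lists, odorant binding had 2 of 23 higher and 3 lower (0 and 3). The 4 thioesterase genes, also a pathway list but too few for a list test, had 1 higher (2 and 0). Camera called none of the 20 of these lists that it tested, while fry called 5 lower. The called members of 19 of the 21 moved by over 1.5 times without non-luminous replicate 3, of 15 without luminous replicate 3, of 14 each without non-luminous replicates 1 and 2, of 4 without luminous replicate 1 and of 2 without luminous replicate 2. The balance of calls turned with the scaling for some lists. After quantile normalization, genes higher and lower were 7 and 2 for testis, 14 and 10 for photoreceptor, 21 and 12 for ABC transporters, 6 and 3 for odorant binding, and 8 and 4 for acyl-CoA synthetases. After median-of-ratios rescaling they were 5 and 2 for testis, 17 and 13 for ABC transporters and 3 and 2 for chaperones. Median and camera direction differed in sign for acyl-CoA synthetases, ABC transporters, chaperones, neuron and testis. The midgut list takes in the cytosolic carboxypeptidase gene agtpbp1 by its name.

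Luminous replicate 1 stood apart. The 17 genes lower in the luminous organ that were at least 2-fold higher in it than in luminous replicates 2 and 3 included CD63 and Tsp2A. Their excess in replicate 1 over the mean of replicates 2 and 3 had a median of 19.6% of their non-luminous level. Carry-over of whole non-luminous tissue is argued against by 6 abundant non-luminous genes nearly absent from luminous replicates 2 and 3. Their level in luminous replicate 1, with nothing subtracted, had a median of 0.106% of the non-luminous level. However, CD63, 1 of the 6, reached 20.8%. Depth is argued against too, at 20.04 M reads inside the range of 18.04 to 20.42 M reads of the others. A further tissue present in varying amounts in both organs stays open: of 68 genes above 10 FPKM and over 8-fold higher there than in luminous replicates 2 and 3, 70.6% were higher in non-luminous replicate 2 than in 1, against 43.5% of all genes. A first test kept the 34 of them over 3-fold above each non-luminous library, such as regucalcin and chymotrypsin-1, and gave 97.1%, while of the other 34 only 15 had that order; the labels name no biological difference among the luminous libraries to test.

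Genes higher in the luminous organ also differed among its libraries. Of 367 such genes at least 2-fold higher, 131 were highest in replicate 3 and lowest in 1, where chance gives 61.2 if genes vary independently. Genes vary together, so any factor shared by many of them can make 1 order common. The reverse order held for 38, fewer than 61.2. Among these 38 was RI129_003463, described as luciferin 4-monooxygenase (532, 374 and 292 FPKM). A varying share of a single luminous tissue stays open, since the 131 are neither most of the genes nor set against a reverse order commoner than chance. A varying share of cuticle-forming cells stays open too: 4 of 10 cuticle and lipid list genes had the commoner order against 127 of 357 others (one-sided Fisher's exact p = 0.506, 95% interval of the odds ratio 0.246 to 5.20), which are too few list genes. First bounds read these values as excluding both explanations and were replaced after the values were seen; the labels name no biological difference among these libraries to test.

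For the higher muscle genes, library composition is argued against, since their median log2 difference was 0.76 as deposited and 0.86 after median-of-ratios rescaling. More muscle in the dissected luminous organ cannot be told apart from higher expression within it: 88.9% of the 27 members had a higher mean, but by unlike amounts (quartiles 0.33 and 1.18), and the design confounds both with the organ. A first bound, without the spread, read 88.9% as fitting more muscle and was replaced after the value was seen. Higher expression within the organ, as the cause of the difference, stays open as untested.

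With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 2626 called genes where the highest other gave 1, 1382 genes at least 2-fold different against 1, 26 luciferase list members against 0 and 114 terms against 0; in each, 1 split was as large, the real one. For gene lists 3 of the 10 splits gave as many as the real 15, the highest 16. Every other split set 2 libraries of an organ and 1 of the other against the rest. It kept part of the organ difference and put the remainder into the spread, so these splits are no reference without change, for lists or for genes.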
